A study of Homo sapiens with 44 samples.

How the data were processed

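Gene expression was measured by RNA sequencing in 44 libraries of H9 human embryonic stem cells differentiated toward cortex, 24 of the Cortecon run and 20 of the Test Case run. Per the labels' protocols, total RNA was extracted with a column kit and the libraries were prepared by either of a pair of service laboratories, which the labels do not assign to samples. The authors deposited a table of normalised values for each run, with 44562 rows each. In these tables the signal is a gene count divided by a size factor per library, as the deposited values themselves show, because every low value of a library was a whole multiple of the value of 1 read. Dividing by that step gave whole reads for 100% of the values (tolerance 0.01 reads). The submitters' processing notes name the hg19 build and the tools DESeq, DESeq2 and edgeR, without versions or roles. The aligner, the counting program, the annotation version and the strandedness are not given in the sources used here, so that reads of antisense, overlapping and closely similar genes cannot be told apart. Of the rows, 22932 carry a number as name and 21629 a name of a catalogue of noncoding transcripts. Numbers were read as NCBI gene numbers, and 22775 of the 22932 were found in a RefSeq gene table of GRCh38.p14, used for names only. Rows whose number found no name held at most 0.111% of the reads of a Cortecon library and 0.098% of a Test Case library. Rows that passed the filter given below entered the tests with or without a name.

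Samples were assigned to run and day from their titles and characteristics. A single Test Case day 7 column was mapped to its day only, because its library number does not match the number in the label, and 0 columns were left unused. The sample descriptions carry library numbers, which fall into series: 86 to 104, 212 to 298, 167 and 168 (day 26), a set marked with a word (day 63) and a series of its own, with higher numbers (Test Case). Cortecon days 0, 7 and 19 have 2 libraries in each of the first 2 series, day 12 lies in 86 to 104, and days 33, 49 and 77 lie in 212 to 298. The meaning of the numbers is not given in the sources used here, and they were treated as possible batches. The reads of Cortecon day 63 and Test Case day 49 were identical, which was found by comparing all pairs of libraries.

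The tests were done on log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and without a block, on all libraries of a run together. Genes with a value of at least 10 in at least 2 libraries of the table were kept, and p-values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Adding 1 makes folds understate the change of low genes. Contrasts of stages took the mean of the day means of each side. The runs were compared in a fit of all 44 libraries as differences between changes from day 0, averaged over days 7, 12 and 19 or over days 33, 49, 63 and 77, and with an F-test over the 7 shared days, because the tables were normalised separately. Of 40 gene lists, 39 were tested with camera at a preset correlation of 0.01, with an estimated correlation as the alternative, and p-values were adjusted over the lists of a comparison. The list of mitochondrially encoded genes had 0 members in the tables and was not tested. In the primary microcephaly list 16 members were measured.

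The comparisons, tests, lists and alternatives, other than those described as added, were chosen before the data were examined. Genes named were, for each Cortecon comparison and each difference between runs, the 6 largest rises and the 6 largest falls among called genes with a mean value of at least 50 and, within the Cortecon run, without overlap between the libraries of both sides. To these came up to 4 called members of each called list or list named for the stage (2 in the Test Case comparisons), chosen by size of change, and marker genes, of which 13 are reported, since some of the genes so chosen are not reported here. Lists were chosen for the text by the smallest camera p, and genes for which a compared group was at 0 in every library were mostly left out of the text, since their fold is a lower bound.

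Alternatives chosen in advance were a pseudocount of 0.5 or 5, no filter, a filter at 50, TMM, quantile and median-ratio scaling, robust variance estimation, fry, replicate letters as a block, the number series as a batch term or one series alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. With edgeR, 13946 genes were called between days 0 and 7, 9861, 10185 and 9742 in the later Cortecon comparisons, 13313, 8766, 11069 and 9290 in the Test Case comparisons, and 7544 and 6483 in the early and late differences between runs. Added after seeing the data were fits without the shared libraries, without day 77, with every library thinned to the reads of the shallowest, and with 1 mean per day and number series. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

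The procedure was tested on simulated reads drawn with the means and depths of the real libraries, with known changes in 200 genes. For the Cortecon comparison of days 0 and 7, over 20093 genes, it recovered 67.2% of 1.5-fold, 80.6% of 2-fold and 95.5% of 4-fold changes and called 0.156% of unchanged genes. For the same days of the Test Case run, over 18498 genes, the shares were 59.7%, 95.5% and 98.5%, with 0.322% of unchanged genes called. For the early difference between runs, over 18178 genes, they were 41.8%, 82.1% and 98.5%, with 0.0946% of unchanged genes called. Far more than 200 genes were called in the real comparisons, so that these shares do not carry over to them. The simulated libraries were also drawn independently, whereas real libraries of a day and number series were closely alike.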

Results

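Gene expression was measured by RNA sequencing while H9 cells, an established human embryonic stem cell line also called WA-09, were turned toward cerebral cortex in culture. The cells were treated with 100 nM LDN193189, an inhibitor of BMP receptors, and 10 uM SB431542, an inhibitor of activin and Nodal receptors, followed by 1 uM cyclopamine, which blocks Hedgehog signalling. The Cortecon run began at about 90% confluency and held 24 libraries, with 4 each on days 0, 7 and 19 and 2 each on days 12, 26, 33, 49, 63 and 77. Its stages were named pluripotency (day 0), neural differentiation (day 7), cortical specification (days 12 and 19), deep layer formation (days 26, 33 and 49) and upper layer formation (days 63 and 77). The Test Case run began at about 65% confluency and held 20 libraries, 2 on each of days 0, 7, 12, 16, 19, 25, 33, 49, 63 and 77, with no stage names. Start density was not varied within a run, so that it and the run cannot be told apart. Values are gene counts divided by a size factor, called normalised reads here, and fold changes are given as log2 of normalised reads plus 1 with the standard error. The libraries held 12536846 to 142010398 reads in the Cortecon table, with at most 49019533 before day 77, and 12536846 to 24021732 reads in the Test Case table. Both libraries of Cortecon day 63 held the same reads as the libraries of Test Case day 49 in all 44562 rows, 21517 and 20373 of them above 0. These libraries were counted once within each run, and the limma total of called genes of each comparison they enter is also given without them. Nothing in the labels says that libraries of a day came from separate cultures. Libraries of a day within a number series differed by 3.57 to 13.1 chi-square units per gene in the Cortecon run, apart from the deeper day 77 pair at 94.7. Pairs across series differed by 31.1 to 84.7 and the pairs of the Test Case run by 2.67 to 32.4, so that p-values measure only the spread between these libraries, which may be technical.

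The stem cell factor POU5F1 stood at 16740.4 ± 1323 normalised reads (mean ± SD, n = 4) on day 0 of the Cortecon run and 95.8 ± 15.5 on day 7 (n = 4). In the Test Case run it went from 6339 ± 155 (n = 2) to 0.404 ± 0.571 on day 7 (n = 2). NANOG, another pluripotency factor, went from 653 ± 65.4 to 2.11 ± 1.64 over the same week of the Cortecon run. PAX6, a regulator of cortical progenitors, went from 85.2 ± 28.4 to 19924 ± 2932 by day 7 and stood at 9856 ± 670.3 on day 77 (n = 2). Its Test Case level was 3115 ± 44.6 on day 7, 4627 ± 344 in the shared libraries of day 49 and 1823 ± 265 on day 77, although levels of the separately normalised tables are not on 1 scale. EMX2, a dorsal telencephalic factor, reached 2442 ± 357 on day 7, whereas EMX1 was highest on day 0 at 129 ± 20.5 and stood at 3.07 ± 0.171 on day 49. TBR1, a deep layer neuron factor, stood at 1.06 ± 0.963 on day 19, 167 ± 44.9 on day 49 and 498 ± 227 on day 77. EOMES, which marks intermediate progenitors in cortex and endoderm or mesoderm precursors in stem cell cultures, was 120.3 ± 104 on day 0 and 166 ± 55.6 on day 77. BCL11B, another deep layer factor, went from 24.8 ± 14.7 on day 12 to 384 ± 31.6 on day 77.

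Of the upper layer factors, CUX1 was highest on day 49, at 9924 ± 136, and CUX2 on day 77, at 1173 ± 2.47 beside 1167 ± 77.7 on day 49. DCX, a microtubule protein of migrating neurons, went from 202 ± 82.0 on day 0 to 7971 ± 577 on day 77, and its Test Case level was highest on day 25 at 12216 ± 457 (n = 2). MKI67, a proliferation marker, stood at 9062 ± 4091 on day 0 and 1956 ± 20.1 on day 77 of the Cortecon run. GFAP, an intermediate filament of astrocytes, was 347 ± 18.2 on day 77 of the Cortecon run and 11616 ± 2511 on day 77 of the Test Case run. In the Test Case run TBR1 stood above 10 only on day 49, at 171 ± 90.9, in the libraries whose reads are also those of Cortecon day 63. Over the 9 Cortecon days 18169 of 19021 genes changed, and over the 10 Test Case days 16921 of 17841 did (limma F-test, adjusted p under 0.05), with 17978 and 16553 without the shared libraries.

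**Figure D1:**
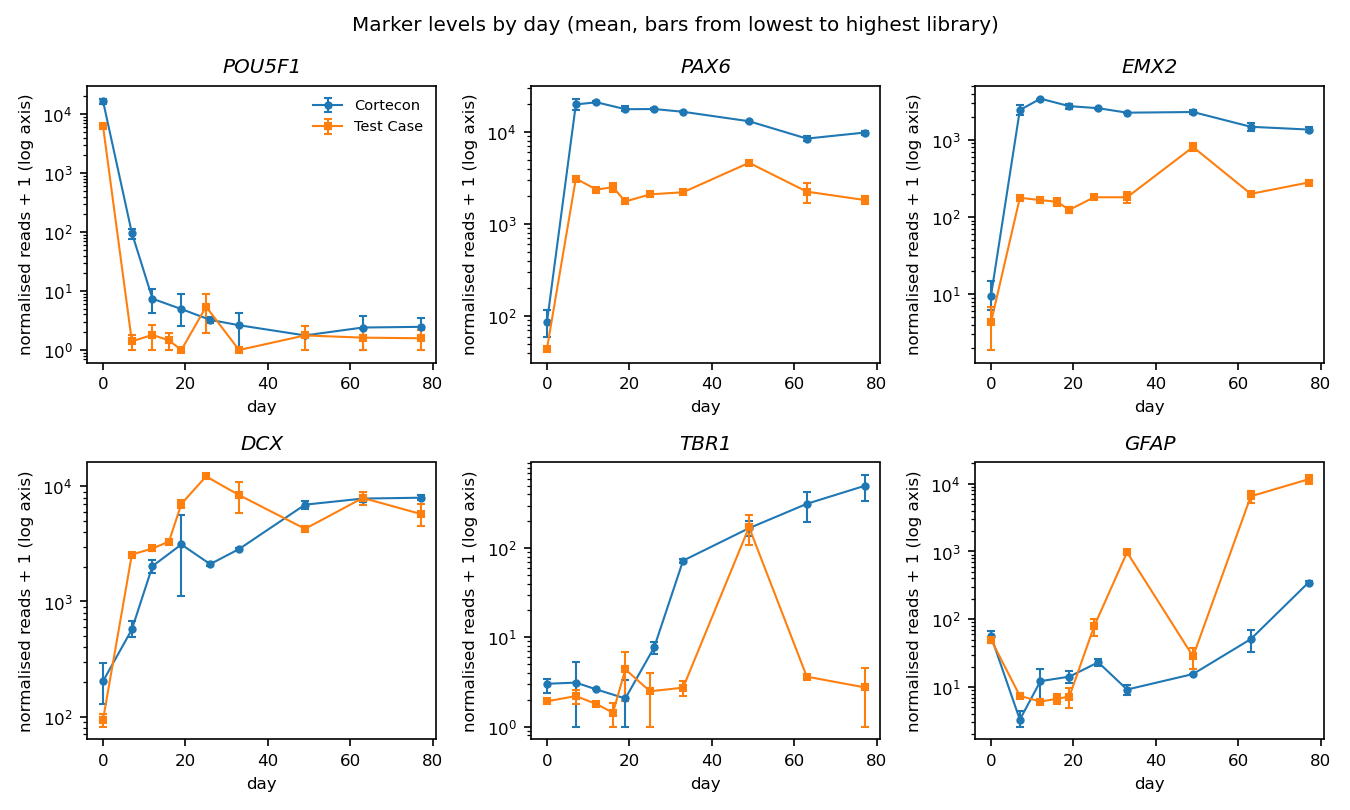
Normalised reads plus 1 (log axis) of POU5F1, PAX6, EMX2, DCX, TBR1 and GFAP against day of culture in the Cortecon (blue) and Test Case (orange) runs. Points are means, bars run from the lowest to the highest library (n = 2 to 4), and the Test Case points of PAX6, TBR1 and EMX2 peak on day 49, whose reads are also those of Cortecon day 63.

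The first Cortecon comparison set day 7 against day 0, the step from pluripotency to neural differentiation. WNT1, a ligand of the midbrain and dorsal midline, rose by 10.54 ± 0.43 (log2 ± SE, n = 4 and 4 libraries, limma adjusted p = 2.5e-14), the largest rise under the naming rule. ZBTB16 (gene 7704), a zinc finger repressor, rose by 9.50 ± 0.33, where the number after "gene" is the NCBI gene number used as row name in the tables. BARHL1 (gene 56751) and LMX1A (gene 4009), homeobox factors of the midbrain and dorsal midline, rose by 9.46 ± 0.29 and 9.30 ± 0.44. MAB21L2, needed for eye development, and NOS2, the inducible nitric oxide synthase, rose by 9.18 ± 0.36 and 9.16 ± 0.29. The largest falls were in CRIPTO (gene 6997), a Nodal co-receptor, at -11.45 ± 0.54 (limma adjusted p = 2.3e-13), and HHLA1, a transcript associated with an endogenous retrovirus, at -11.04 ± 0.47. The Nodal inhibitors LEFTY1 and LEFTY2 stood at -10.76 ± 0.65 and -9.87 ± 0.72. CRIPTO3 changed by -9.78 ± 0.40, a value that is uncertain because this gene is a near copy of CRIPTO and can share its reads. The neuropeptide gene GAL stood at -9.08 ± 0.32.

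Counts of the gene lists are out of the members measured, and values of genes named beside them are log2 changes ± SE. In the neuroepithelium list 21 of 24 rose and 2 fell (camera adjusted p = 1.7e-08, and adjusted p = 0.00019 with an estimated correlation). The forebrain homeobox gene LHX5 rose by 9.01 ± 0.15, the Notch effector HES5 by 8.48 ± 0.44 and the early neural factor SOX1 by 8.25 ± 0.24. Of the dorsal telencephalon genes, 16 of 20 rose and 1 fell (camera adjusted p = 3.5e-06, and adjusted p = 0.027 with an estimated correlation). FEZF2 stood at 8.45 ± 0.20, EMX2 at 8.07 ± 0.18 and PAX6 at 7.90 ± 0.16. In the pluripotency list 16 of 19 fell and 3 rose (camera adjusted p = 5.3e-05, but adjusted p = 0.096 with an estimated correlation). NANOG stood at -7.93 ± 0.38, POU5F1 at -7.44 ± 0.49 and GDF3, a TGF-beta family ligand, at -7.26 ± 0.34. For ribosomal proteins, 28 of 36 rose (camera adjusted p = 0.00012, but adjusted p = 0.64 with an estimated correlation). RPL18 rose by 0.88 ± 0.08. Nodal and left-right target genes went down together, in that 9 of 10 fell (camera adjusted p = 0.00074, and adjusted p = 0.027 with an estimated correlation). The Nodal antagonist CER1 stood at -9.02 ± 0.88 and NODAL itself at -5.66 ± 0.45. For the Notch pathway 13 of 18 rose and 3 fell (camera adjusted p = 0.0015, and adjusted p = 0.027 with an estimated correlation). The ligand DLL1 stood at 6.74 ± 0.20 and the target HES4 at 4.23 ± 0.49.

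The midbrain list, which holds WNT1, BARHL1 and LMX1A, also moved, and 10 of 15 rose and 1 fell (camera adjusted p = 0.0015, but adjusted p = 0.25 with an estimated correlation). In the cell cycle list 24 of 32 fell and 3 rose (camera adjusted p = 0.0015, but adjusted p = 0.64 with an estimated correlation). The nucleotide enzyme RRM2 stood at -1.61 ± 0.12 and the replication helicase subunit MCM5 at -1.56 ± 0.09. Of the retina and pigment epithelium genes 14 of 21 rose and 2 fell (camera adjusted p = 0.0015, but adjusted p = 0.083 with an estimated correlation). The eye field factors SIX3 and RAX stood at 5.74 ± 0.27 and 5.16 ± 0.61. Choroid plexus and cortical hem genes followed, as 14 of 23 rose and 4 fell (camera adjusted p = 0.0019, but adjusted p = 0.45 with an estimated correlation). RSPO2 and WNT3A, WNT pathway ligands, stood at 8.99 ± 0.18 and 7.76 ± 0.38. Among WNT targets 11 of 13 rose and 2 fell (camera adjusted p = 0.0045, but adjusted p = 0.64 with an estimated correlation). Among neural crest and peripheral neuron genes 14 of 19 rose and 4 fell (camera adjusted p = 0.014, but adjusted p = 0.64 with an estimated correlation, and adjusted p = 0.069 within series 212 to 298). PAX3, a neural crest and dorsal neural tube factor, rose by 9.05 ± 0.17. Camera also called the autism-associated list up (18 of 29 rose and 4 fell, adjusted p = 0.014, but adjusted p = 0.64 with an estimated correlation, and adjusted p = 0.13 within series 86 to 104). It called p53 and DNA damage genes down (12 of 16 fell and 1 rose, adjusted p = 0.029, but adjusted p = 0.64 with an estimated correlation). FGF pathway feedback genes were also called down (11 of 16 fell and 3 rose, adjusted p = 0.045, but adjusted p = 0.45 with an estimated correlation, and adjusted p = 0.066 within series 212 to 298 and 0.058 with a stricter filter). Adjusted over the list alone, the counts of risen and fallen members were the same.

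In all, 14101 of 19021 genes changed between day 0 and day 7, 6741 up and 7360 down, and 3605 and 3797 of them by at least 2-fold (limma, adjusted p under 0.05). Within the number series 86 to 104 the count was 13511, and within 212 to 298 it was 14949, with 2 libraries a day in each. EMX1, TBR1, CUX2 and MKI67 did not pass the test (-0.10, -0.18, 0.01 and -0.03). Within a single series, however, CUX2 fell in 86 to 104 (-0.37) and rose in 212 to 298 (0.38), and MKI67 did likewise (-0.88 and 0.81). With 1 mean per day and number series, an alternative chosen after seeing the data, 9286 genes passed.

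The second comparison set cortical specification, days 12 and 19, against day 7. CDC20B, a gene of the locus that drives formation of multiciliated cells, rose by 10.00 ± 0.28 (log2 ± SE, n = 6 and 4 libraries, limma adjusted p = 1.2e-15). TEKT1 and CFAP52, parts of motile cilia, rose by 8.29 ± 0.28 and 7.81 ± 0.30. The neuropeptide gene SST rose by 8.68 ± 0.42 and SLC17A6, a vesicular glutamate transporter, by 7.79 ± 0.44. Among the largest falls were HES3, a repressor of neural differentiation, at -5.86 ± 0.38 (limma adjusted p = 1.7e-10), and the calcium sensor VSNL1 at -5.68 ± 0.18. Others were GARIN1B at -5.47 ± 0.37, the cadherin CDH9 at -5.04 ± 0.31, the matrix protein PAPLN at -4.93 ± 0.19 and SEZ6 at -4.71 ± 0.31.

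No list call of this comparison was kept with an estimated correlation, and camera with the preset correlation called 7. Ribosomal proteins went down, in that 30 of 36 fell (camera adjusted p = 1.2e-10, but adjusted p = 0.67 with an estimated correlation). RPS2 stood at -0.89 ± 0.09 and RPS6 at -0.79 ± 0.08. Pluripotency genes fell further, and 13 of 19 fell (camera adjusted p = 4.8e-05, but adjusted p = 0.51 with an estimated correlation). PRDM14 stood at -4.20 ± 0.28 and POU5F1 at -4.17 ± 0.46. In the p53 and DNA damage list 13 of 16 rose (camera adjusted p = 0.00024, but adjusted p = 0.67 with an estimated correlation). The stress cytokine GDF15 stood at 3.38 ± 0.34 and the cell cycle inhibitor CDKN1A at 3.06 ± 0.25. For pan-neuronal genes 14 of 24 rose and 3 fell (camera adjusted p = 0.0087, but adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.19 within series 212 to 298). The stathmin STMN4 rose by 5.47 ± 0.35 and the neurofilament NEFM by 5.20 ± 0.38. Of the choroid plexus and cortical hem genes 12 of 23 rose and 3 fell (camera adjusted p = 0.0087, but adjusted p = 0.67 with an estimated correlation). The chloride channel CLIC6 rose by 4.32 ± 0.19 and WNT2B by 3.13 ± 0.35. In the cell cycle list 15 of 32 fell and 2 rose (camera adjusted p = 0.0087, but adjusted p = 0.80 with an estimated correlation, and adjusted p = 0.14 with quantile scaling). MCM5 stood at -0.95 ± 0.08 and cyclin D1, CCND1, at 0.80 ± 0.10. Among BMP targets 8 of 14 rose and 1 fell (camera adjusted p = 0.043, but adjusted p = 0.80 with an estimated correlation, and adjusted p = 0.062 with the series as a batch term). BAMBI rose by 2.66 ± 0.20 and SMAD7 by 1.82 ± 0.12. Adjusted over the list alone, the counts of risen and fallen members were the same except for ribosomal proteins (0 and 31) and choroid plexus and cortical hem (13 and 3).

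Of 19021 genes, 10055 changed, 5320 up and 4735 down (limma, adjusted p under 0.05), 2601 and 879 by at least 2-fold. Quantile scaling gave 4576 up and 6137 down. Within series 86 to 104 the count was 11111, within 212 to 298, which lacks day 12, it was 13228, and with the series as a batch term 10133. With 1 mean per day and number series 3209 genes passed. EMX1 fell (-4.35 ± 0.47) and DCX and GFAP rose by 2.00 ± 0.34 and 1.90 ± 0.29. GFAP stood at 2.31 normalised reads on day 7, 11.2 on day 12 and 13.2 on day 19, near the filter of 10 and below its 55.4 on day 0. DCX ranged from 1123 to 5587 between the libraries of day 19. PAX6 lay at -0.04 without passing the test. PAX6 nevertheless rose by 0.17 within series 86 to 104 and changed by -0.40 within series 212 to 298, both past the test there (limma adjusted p = 0.0077 and 0.00014).

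The third comparison set deep layer formation, days 26, 33 and 49, against cortical specification, days 12 and 19. Lens crystallins led the rises, with CRYBB1 at 8.38 ± 0.26 (log2 ± SE, n = 6 and 6 libraries, limma adjusted p = 4.2e-14) and CRYAA at 7.58 ± 0.28. They were followed by CRYBB3 at 6.72 ± 0.52, CRYBA4 at 6.66 ± 0.26 and CRYBA2 at 5.92 ± 0.48. Because crystallins of a family resemble each other and can share reads, the values of single members are uncertain. FGF17, a growth factor of the anterior forebrain midline, rose by 6.11 ± 0.46. The largest falls were in FOXD3, a neural crest factor, at -6.57 ± 0.34 (limma adjusted p = 1.7e-11), and CDH19, a cadherin of glial precursors of peripheral nerves, at -5.55 ± 0.35. PRSS56 stood at -5.41 ± 0.49, LIN28A, an RNA-binding protein of early embryonic cells, at -5.38 ± 0.19, INSC, which orients the mitotic spindle, at -4.69 ± 0.46, and POU4F1, a sensory neuron factor, at -4.63 ± 0.38. Of the layer markers, TBR1 rose by 4.34 ± 0.37, BCL11B by 1.65 ± 0.22 and EOMES by 3.14 ± 0.67.

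Camera called 6 lists in this comparison, and none of these calls was kept with an estimated correlation. For the cell cycle 30 of 32 fell and 2 rose (camera adjusted p = 6.7e-17, but adjusted p = 0.20 with an estimated correlation). The survivin gene BIRC5 stood at -1.74 ± 0.12 and the regulator E2F1 at -1.60 ± 0.11, while CCND2, another D cyclin, rose by 1.54 ± 0.14. Neural crest and peripheral neuron genes went down, in that 14 of 19 fell and 1 rose (camera adjusted p = 8.8e-06, but adjusted p = 0.52 with an estimated correlation). SOX10 stood at -3.97 ± 0.17 among them. In the pluripotency list 12 of 19 fell and 1 rose (camera adjusted p = 2.8e-05, but adjusted p = 0.20 with an estimated correlation), led by LIN28A and VRTN (-3.58 ± 0.35). Of the primary microcephaly genes, many of which act at the spindle and centrosome, 12 of 16 fell and 1 rose (camera adjusted p = 2.8e-05, but adjusted p = 0.20 with an estimated correlation). The kinesin CENPE stood at -1.43 ± 0.17 and the spindle pole protein ASPM at -1.32 ± 0.14. Mesoderm and mesenchyme genes, which mark cells other than cortex, went up together, in that 15 of 25 rose and 1 fell (camera adjusted p = 0.00048, but adjusted p = 0.74 with an estimated correlation). The matrix proteins DCN, OGN and POSTN stood at 4.65 ± 0.57, 4.58 ± 0.44 and 4.29 ± 0.45. Among astrocyte genes 12 of 20 rose and 2 fell (camera adjusted p = 0.046, but adjusted p = 0.51 with an estimated correlation, and adjusted p = 0.052 with quantile scaling). SPARCL1 rose by 3.43 ± 0.23 and ATP1B2 by 1.64 ± 0.28. The lists named for this stage were not called as groups. For the deep layer list 12 of 21 rose and 6 fell (camera adjusted p = 0.47), and for the intermediate progenitor list 6 of 16 fell and 4 rose (camera adjusted p = 0.42). Adjusted over the list alone, the counts of risen and fallen members were the same except for neural crest and peripheral neurons (2 and 16), pluripotency (2 and 12), mesoderm and mesenchyme (17 and 1), astrocytes (13 and 2), deep layer neurons (12 and 8) and intermediate progenitors (5 and 6).

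In this comparison 10070 of 19021 genes changed, 5266 up and 4804 down (limma, adjusted p under 0.05), 1719 and 979 by at least 2-fold. Day 26 stands in a number series of its own and day 12 with some of day 19. Within series 212 to 298, days 33 and 49 against day 19, 11236 genes changed, with 10221 in the fit with series as a batch term. With 1 mean per day and series 2967 genes passed.

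The last Cortecon comparison set upper layer formation, days 63 and 77, against days 26, 33 and 49. CRYBB2 rose by 8.30 ± 0.41 (log2 ± SE, n = 4 and 6 libraries, limma adjusted p = 1.5e-11), CRYBA2 by 7.78 ± 0.52, CRYGA by 6.66 ± 0.40 and CRYBA1 by 6.02 ± 0.29. The same caution about reads shared within the crystallin family applies. SMR3B, a gene of salivary secretions, rose by 7.06 ± 0.40, and the complement gene C4B by 5.70 ± 0.31, which is uncertain because of a nearly identical paralog. Among the falls, LIN28A stood at -5.87 ± 0.21 (limma adjusted p = 1.5e-13), its relative LIN28B at -3.63 ± 0.07 and the stem cell genes DPPA4 and SALL4 at -5.41 ± 0.24 and -4.39 ± 0.11. BARHL1, which had risen by day 7, stood at -4.71 ± 0.27. TBR1 rose by 3.05 ± 0.40, BCL11B by 1.73 ± 0.24, DCX by 1.19 ± 0.33 and GFAP by 3.13 ± 0.29, while PAX6 and EMX2 fell (-0.78 ± 0.14 and -0.75 ± 0.16). CUX1 and CUX2, at -0.03 and 0.20, did not pass the test.

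Of the cell cycle genes 29 of 32 fell and 1 rose (camera adjusted p = 7.8e-13, but adjusted p = 0.19 with an estimated correlation). The mitotic kinase AURKB stood at -1.62 ± 0.16 and the ubiquitin enzyme UBE2C at -1.44 ± 0.18. In the pluripotency list 12 of 19 fell (camera adjusted p = 3.4e-07, but adjusted p = 0.054 with an estimated correlation). For ribosomal proteins 26 of 36 fell and 1 rose (camera adjusted p = 1.2e-06, but adjusted p = 0.65 with an estimated correlation). RPS19 stood at -0.74 ± 0.10. For neuroepithelium 16 of 24 fell and 3 rose, a call kept with both correlations (camera adjusted p = 0.00020, and adjusted p = 0.011 with an estimated correlation). SOX3 stood at -2.32 ± 0.20 and LHX5 at -2.06 ± 0.14. Astrocyte genes rose, as 13 of 20 rose and 1 fell (camera adjusted p = 0.00058, but adjusted p = 0.083 with an estimated correlation). The adhesion receptor CD44 stood at 3.38 ± 0.23 and the glutamate transporter SLC1A3 at 3.35 ± 0.13. Of the retina and pigment epithelium genes 15 of 21 rose and 1 fell (camera adjusted p = 0.00070, but adjusted p = 0.064 with an estimated correlation). RPE65, an enzyme of the visual cycle, stood at 2.91 ± 0.28 and the pigment enzymes TYRP1 and TYR at 2.88 ± 0.38 and 2.88 ± 0.54. In the Cajal-Retzius and preplate list 12 of 13 rose and 1 fell (camera adjusted p = 0.0039, but adjusted p = 0.054 with an estimated correlation). The calcium-binding protein CALB2 stood at 2.73 ± 0.25. Dorsal telencephalon genes fell, in that 9 of 20 fell and 1 rose (camera adjusted p = 0.0062, but adjusted p = 0.19 with an estimated correlation). FEZF2 stood at -1.68 ± 0.18. Mesoderm and mesenchyme genes rose again, as 14 of 25 rose and 2 fell (camera adjusted p = 0.011, but adjusted p = 0.71 with an estimated correlation). OGN rose by 5.18 ± 0.48.

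Among intermediate progenitor genes 11 of 16 rose and 3 fell (camera adjusted p = 0.011, but adjusted p = 0.30 with an estimated correlation, and adjusted p = 0.085 without day 77). The opioid precursor PENK rose by 4.43 ± 0.47 and the proneural factor NEUROD1 by 3.60 ± 0.56. Primary microcephaly genes were called down (9 of 16 fell and 1 rose, camera adjusted p = 0.0057, but adjusted p = 0.30 with an estimated correlation). So were p53 and DNA damage genes (8 of 16 fell and 1 rose, camera adjusted p = 0.033, but adjusted p = 0.86 with an estimated correlation, and adjusted p = 0.14 without day 77 and 0.14 with quantile scaling). The upper layer list, named for this stage, was not called (8 of 21 rose and 3 fell, camera adjusted p = 0.58), nor was the deep layer list (10 of 21 rose and 5 fell, camera adjusted p = 0.38). Adjusted over the list alone, the counts of risen and fallen members were the same except for ribosomal proteins (1 and 27), astrocytes (14 and 1) and upper layer neurons (8 and 4). In all 9384 of 19021 genes changed, 4951 up and 4433 down (limma, adjusted p under 0.05), 1956 and 823 by at least 2-fold. Quantile scaling, which moved the median of all genes by -0.10 (log2), gave 4104 up and 6049 down. Without day 63, whose reads also stand under Test Case day 49, the count was 7771. MKI67 there lost its call (-0.52, limma adjusted p = 0.12) and GFAP stood at 4.56, while the list calls named above were kept. Without day 77, with its deeper libraries, the count was 7042. Within series 212 to 298, day 77 against days 33 and 49, 11035 genes changed. With 1 mean per day and series 1907 passed, and DCX, PAX6 and EMX2 lost their calls (limma adjusted p = 0.19, 0.090 and 0.11). The calls of DCX and MKI67 were also lost with the batch term, without days 26 and 63 (limma adjusted p = 0.073 and 0.31), where MKI67 stood at -0.38.

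**Figure D2:**
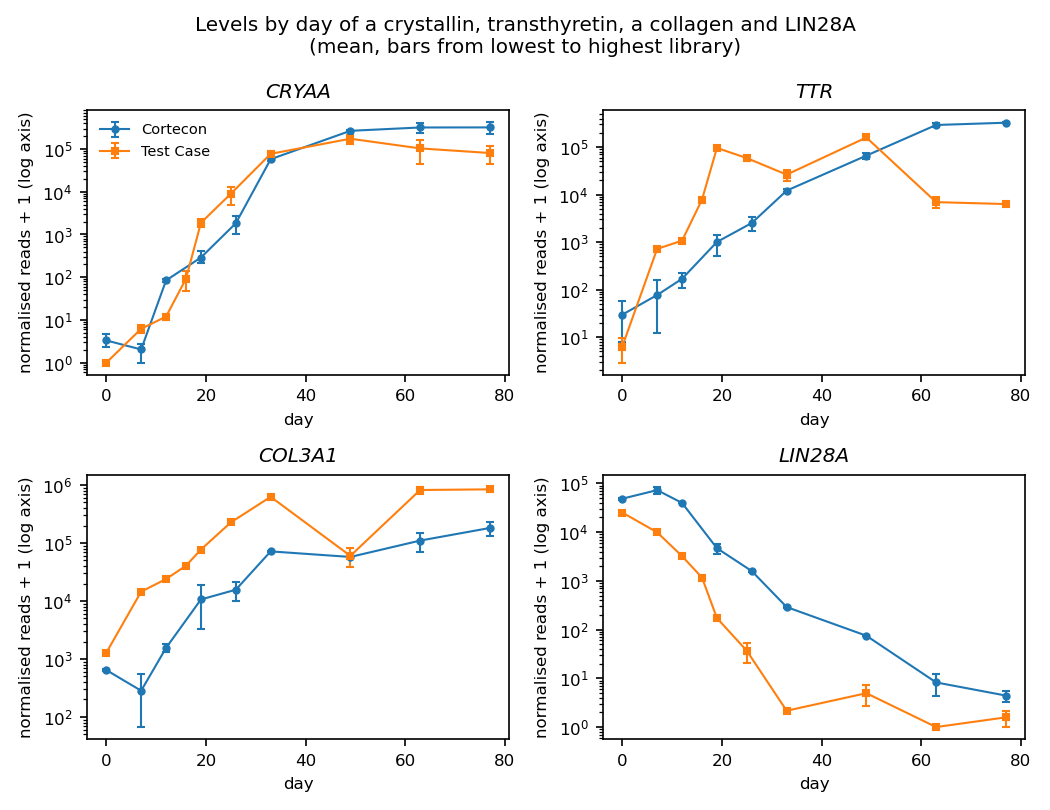
Normalised reads plus 1 (log axis) of CRYAA, TTR, COL3A1 and LIN28A against day of culture in the Cortecon (blue) and Test Case (orange) runs, as means with bars from the lowest to the highest library (n = 2 to 4). CRYAA stood at 320415 ± 142940.0 and LIN28A at 3.43 ± 1.61 on day 77 of the Cortecon run, and the Test Case points of COL3A1 and TTR on day 49 lie apart from days 33 and 63 and on the Cortecon side, being the reads of Cortecon day 63.

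**Figure D3:**
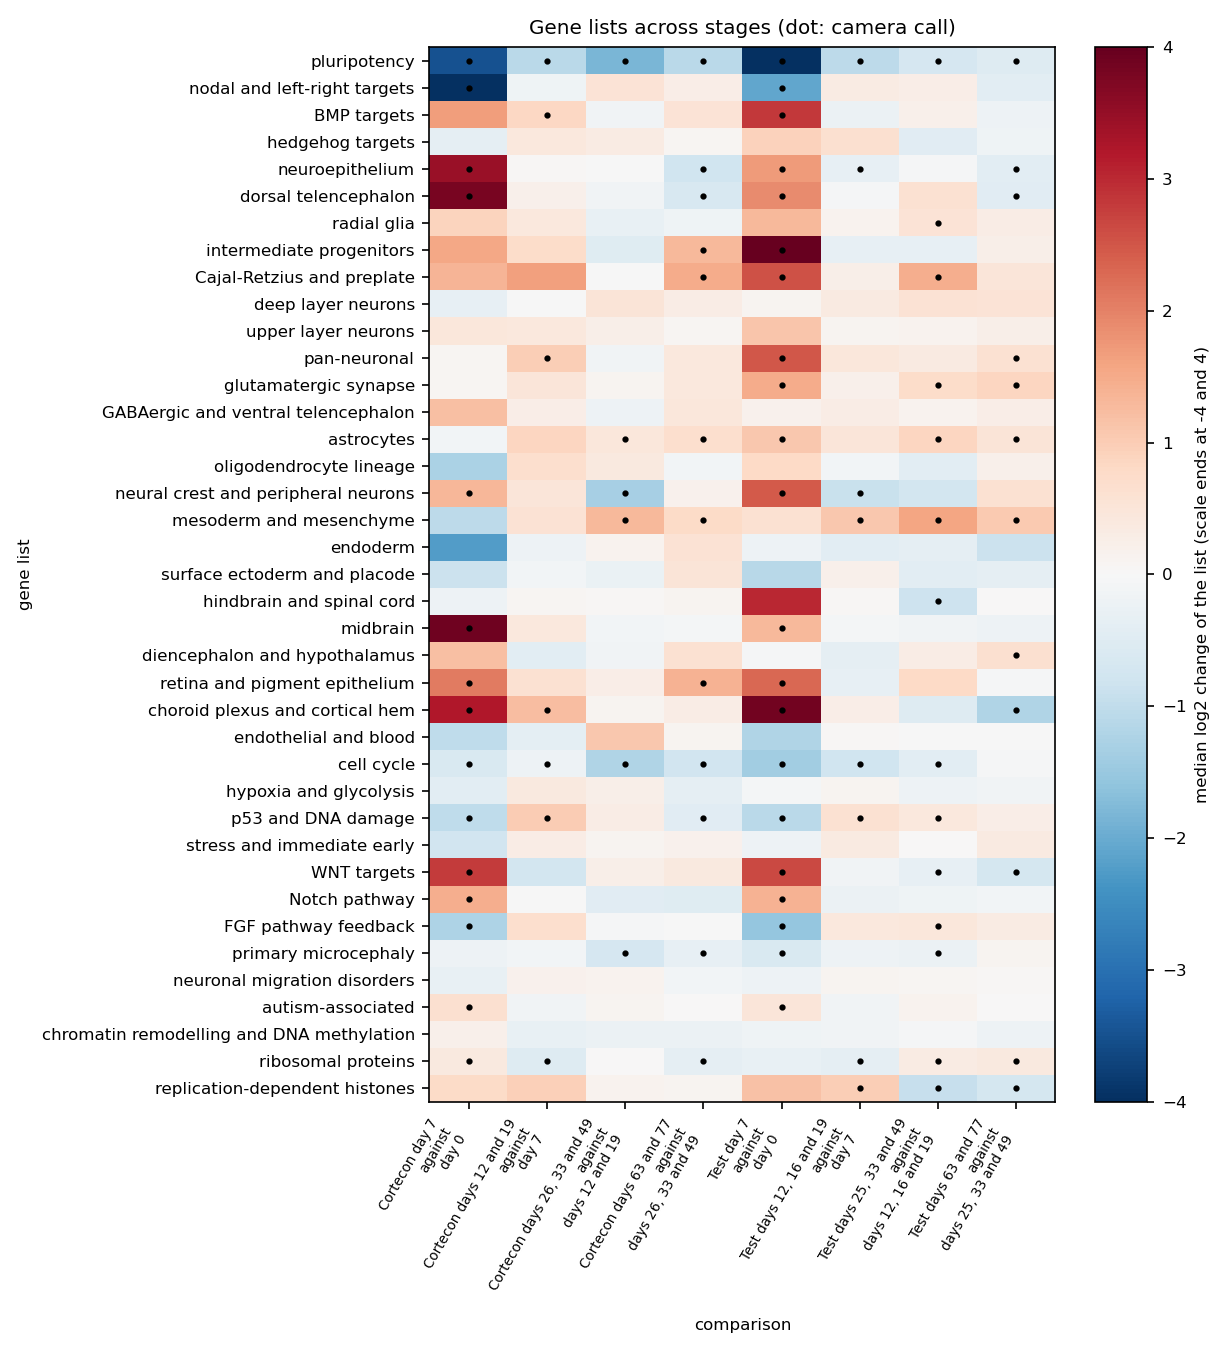
Median log2 change of each gene list (rows) in the stage comparisons of the Cortecon and Test Case runs (columns), as a colour scale in log2 units. Dots mark lists called by camera with a preset correlation, and the cell cycle and pluripotency lists are negative in all 4 Cortecon comparisons.

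The Test Case run was compared in the same way, by days without stage names, with 2 libraries a day. From day 0 to day 7 the cell cycle list was called down (31 of 32 fell, camera adjusted p = 4.9e-09, but adjusted p = 0.18 with an estimated correlation). The choroid plexus and cortical hem list was called up (20 of 23 rose and 3 fell, camera adjusted p = 8.5e-07, but adjusted p = 0.063 with an estimated correlation). RRM2 fell (-2.39 ± 0.10, log2 ± SE, n = 2 and 2), LMX1A rose by 9.92 ± 0.17 and GDF7, a BMP ligand of the dorsal midline, by 9.17 ± 0.28. Pluripotency genes fell, as 18 of 19 fell (camera adjusted p = 7.7e-06, but adjusted p = 0.063 with an estimated correlation). POU5F1 stood at -12.20 ± 0.73. Neural crest and peripheral neuron genes rose, as 16 of 20 rose (camera adjusted p = 0.00015, but adjusted p = 0.18 with an estimated correlation). TFAP2B rose by 6.93 ± 0.41. Retina and pigment epithelium genes were called up as well (15 of 20 rose, camera adjusted p = 0.00036, but adjusted p = 0.063 with an estimated correlation). The pigment enzyme DCT rose by 9.99 ± 0.38. Camera called 21 lists here, none of them with an estimated correlation, and 13301 of 17841 genes changed, 6520 up and 6781 down (limma). Counts of the named lists adjusted over the list alone were the same.

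From day 7 to days 12, 16 and 19 the cell cycle list fell further (29 of 32 fell and 1 rose, camera adjusted p = 8.6e-15, but adjusted p = 0.32 with an estimated correlation). FOXM1, a mitotic regulator, stood at -1.26 ± 0.09 (n = 6 and 2). For ribosomal proteins 34 of 36 fell (camera adjusted p = 3.6e-09, but adjusted p = 0.57 with an estimated correlation). Mesoderm and mesenchyme genes rose, as 17 of 23 rose (camera adjusted p = 8.9e-07, but adjusted p = 0.32 with an estimated correlation). The collagen crosslinking enzyme LOX rose by 3.49 ± 0.11. A further list called up was p53 and DNA damage (13 of 16 rose, camera adjusted p = 5.2e-05, but adjusted p = 0.32 with an estimated correlation). CDKN1A rose by 2.53 ± 0.12. In this step 8274 genes changed, 4491 up and 3783 down (limma), and quantile scaling gave 3835 up and 4969 down. Counts of the named lists adjusted over the list alone were the same except for cell cycle (2 and 30), mesoderm and mesenchyme (17 and 1) and p53 and DNA damage (14 and 0), risen and fallen in that order.

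From there to days 25, 33 and 49 ribosomal proteins rose (34 of 36 rose, camera adjusted p = 6.1e-08, but adjusted p = 0.43 with an estimated correlation). RPLP0 rose by 0.54 ± 0.05 (n = 6 and 6). In the mesoderm and mesenchyme list 16 of 23 rose and 3 fell (camera adjusted p = 1.1e-05, but adjusted p = 0.30 with an estimated correlation). OGN rose by 7.07 ± 0.32 and DCN by 4.63 ± 0.14. In the cell cycle list 26 of 32 fell and 1 rose (camera adjusted p = 1.3e-05, but adjusted p = 0.43 with an estimated correlation). Glutamatergic synapse genes rose (17 of 25 rose and 3 fell, camera adjusted p = 0.0018, but adjusted p = 0.43 with an estimated correlation). The neuronal factor NEUROD6 rose by 4.55 ± 0.50. Here 11008 genes changed, 5281 up and 5727 down (limma), and 11037 without day 49, whose reads are those of Cortecon day 63. Without day 49 PAX6 went from 0.35 to -0.0163 and EMX2 from 1.00 to 0.28, and both calls were lost (limma adjusted p = 0.91 and 0.33). The pan-neuronal list (13 of 24 rose and 5 fell, camera adjusted p = 0.065) became called up without day 49 (camera adjusted p = 6.5e-05). The list calls named for this step were kept without day 49. Counts of the named lists adjusted over the list alone were the same except for glutamatergic synapse (18 and 3) and pan-neuronal (15 and 6), risen and fallen in that order.

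In the last step, days 63 and 77 against days 25, 33 and 49, ribosomal proteins rose (33 of 36 rose, camera adjusted p = 2.0e-10, but adjusted p = 0.44 with an estimated correlation). RPLP0 rose by 0.73 ± 0.06 (n = 4 and 6). The choroid plexus and cortical hem list was called down (18 of 23 fell and 1 rose, camera adjusted p = 5.8e-08, but adjusted p = 0.056 with an estimated correlation). TTR, the transthyretin gene abundant in choroid plexus, stood at -3.24 ± 0.25. WNT targets fell (11 of 13 fell, camera adjusted p = 3.5e-05, but adjusted p = 0.056 with an estimated correlation). TCF7 stood at -1.69 ± 0.11, and GFAP rose by 6.10 ± 0.24 (limma adjusted p = 9.1e-12). The earlier side of this step includes the shared libraries of day 49, which enlarged the changes of GFAP and TTR. GFAP stood at 27.3 normalised reads on day 49, beside 77.4 on day 25 and 970 on day 33. TTR took 0.726% and 0.915% of the reads in the day 49 libraries, and 0.0881% to 0.352% on days 25 and 33. Pan-neuronal genes were called up (17 of 24 rose, camera adjusted p = 2.2e-05, but adjusted p = 0.51 with an estimated correlation, and adjusted p = 0.38 without day 49). In this step 9480 genes changed, 4741 up and 4739 down (limma), and 7400 without day 49. Counts of the named lists adjusted over the list alone were the same except for ribosomal proteins (34 and 0) and choroid plexus and cortical hem (2 and 18), risen and fallen in that order.

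The runs were then set against each other as changes from their own day 0, because the 2 tables were normalised separately. A difference in scale between the tables cancels in this way only for genes well above the added 1. In the first of the shared libraries 1 read stood at 1.62 normalised reads in the Cortecon table and 0.882 in the Test Case table. For genes near 0 on a compared day, part of the difference can therefore be scale alone. Gene lists with such members share this limit. Positive differences mean a higher change in the Cortecon run. On the shared days 7, 12 and 19 WNT7B, a WNT ligand, was higher in the Cortecon run by 7.27 ± 0.29 (log2 ± SE, 10 Cortecon and 6 Test Case libraries against 4 and 2 of day 0, limma adjusted p = 3.9e-17). FEZF1, a forebrain factor, was higher by 6.66 ± 0.60, NR5A1, a nuclear receptor, by 6.51 ± 0.65, NOS2 by 6.44 ± 0.41 and SIX3 by 6.34 ± 0.49. Lower in the Cortecon run were SOST, a WNT inhibitor, at -6.89 ± 0.62 (limma adjusted p = 4.0e-10), the muscle protein MYBPC1 at -6.48 ± 0.65, TTR at -6.48 ± 0.90 and TMEM26 at -5.83 ± 0.48. PAX6 and EMX2 were higher by 2.15 ± 0.22 and 2.87 ± 0.33 and DCX and BCL11B lower at -2.42 ± 0.45 and -1.62 ± 0.32.

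Of the cell cycle genes 30 of 32 were higher in the Cortecon run (camera adjusted p = 1.2e-14, but adjusted p = 0.12 with an estimated correlation). UBE2C was higher by 1.59 ± 0.25 and BIRC5 by 1.54 ± 0.18. In the neuroepithelium list 21 of 24 were higher (camera adjusted p = 1.8e-12, and adjusted p = 2.2e-06 with an estimated correlation). LHX5 was higher by 6.11 ± 0.35. For ribosomal proteins 35 of 36 were higher (camera adjusted p = 4.7e-11, but adjusted p = 0.35 with an estimated correlation). RPS19 was higher by 0.91 ± 0.14. Of the dorsal telencephalon genes 16 of 20 were higher and 2 were lower (camera adjusted p = 1.3e-07, and adjusted p = 0.0056 with an estimated correlation). FEZF2 was higher by 5.92 ± 0.70. In the pan-neuronal list 19 of 24 were lower and 3 were higher (camera adjusted p = 6.4e-05, but adjusted p = 0.35 with an estimated correlation). The RNA-binding protein ELAVL3 stood at -3.01 ± 0.54. Histone genes of the replication-dependent type were lower (9 of 13 were lower, camera adjusted p = 0.0019, and adjusted p = 0.027 with an estimated correlation). Nodal and left-right targets were lower as well (8 of 10 were lower and 1 was higher, camera adjusted p = 0.0023, and adjusted p = 0.026 with an estimated correlation). Mesoderm and mesenchyme genes, markers of cells other than cortex, were lower too (14 of 23 were lower and 2 were higher, camera adjusted p = 0.0034, but adjusted p = 0.51 with an estimated correlation). Primary microcephaly genes were called higher (11 of 16 were higher, camera adjusted p = 0.011, but adjusted p = 0.35 with an estimated correlation). So were FGF pathway feedback genes (11 of 16 were higher and 1 was lower, camera adjusted p = 0.028, but adjusted p = 0.35 with an estimated correlation, and adjusted p = 0.092 with quantile scaling). Pluripotency genes were the last list called higher (10 of 19 were higher and 1 was lower, camera adjusted p = 0.028, but adjusted p = 0.35 with an estimated correlation, and adjusted p = 0.055 with reads thinned to the shallowest library). When adjusted over the list alone, the higher and lower members were the same except for pluripotency (10 and 2). In all 8074 of 17640 genes differed, 4165 higher and 3909 lower in the Cortecon run (limma, adjusted p under 0.05). The Cortecon libraries of these days come from both number series and the Test Case libraries from another, and run, start density and library set cannot be told apart.

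On days 33, 49, 63 and 77 the change from day 0 was higher in the Cortecon run for MMRN1, a vessel protein, by 7.26 ± 0.58 (log2 ± SE, 8 and 8 libraries against 4 and 2 of day 0, limma adjusted p = 4.4e-11). On each side 2 of the 8 libraries hold the shared reads, of Cortecon day 63 and Test Case day 49. The standard errors and p-values of the late differences treat them as independent libraries. SIX3 was higher by 6.64 ± 0.48, LGI1, a secreted synaptic protein, by 5.63 ± 0.30, and FEZF2 by 5.48 ± 0.69. Lower were ITGBL1 at -5.40 ± 0.81, GFAP at -5.07 ± 0.43 (limma adjusted p = 1.3e-10), and MIR9-1HG, the host gene of a neural microRNA, at -4.98 ± 0.58. CD34, a marker of vessels and stromal cells, stood at -4.87 ± 0.56, EBF2, a factor of mesenchyme and early neurons, at -4.63 ± 0.69, and OGN at -4.55 ± 0.71, whose call was lost with edgeR (edgeR adjusted p = 0.15). PAX6 was higher by 1.30 ± 0.21, whereas TBR1 at 4.09 ± 0.71 lost its call with edgeR (edgeR adjusted p = 0.13).

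For the neuroepithelium list 18 of 24 were higher and 1 was lower in the Cortecon run (camera adjusted p = 2.5e-09, and adjusted p = 2.1e-05 with an estimated correlation). ZBTB16 was higher by 4.77 ± 0.42. In the pan-neuronal list 17 of 24 were lower and 1 was higher (camera adjusted p = 5.7e-08, but adjusted p = 0.35 with an estimated correlation). The neuronal splicing factor RBFOX3 stood at -2.53 ± 0.31. Of the dorsal telencephalon genes 15 of 20 were higher and 2 were lower (camera adjusted p = 2.7e-06, and adjusted p = 0.014 with an estimated correlation). Choroid plexus and cortical hem genes were higher (15 of 23 were higher and 2 were lower, camera adjusted p = 0.00020, but adjusted p = 0.41 with an estimated correlation). RSPO2 was higher by 4.74 ± 0.31 and WNT3A by 4.36 ± 0.49. Ribosomal proteins were called lower (15 of 36 were lower, camera adjusted p = 0.00036, but adjusted p = 0.81 with an estimated correlation, and adjusted p = 0.059 without the shared libraries). RPS18 stood at -0.61 ± 0.14. Glutamatergic synapse genes were lower (12 of 25 were lower and 2 were higher, camera adjusted p = 0.0018, but adjusted p = 0.52 with an estimated correlation). WNT targets were called higher (7 of 13 were higher, camera adjusted p = 0.0029, but adjusted p = 0.64 with an estimated correlation). Nodal and left-right targets were called lower (5 of 10 were lower and 1 was higher, camera adjusted p = 0.013, but adjusted p = 0.089 with an estimated correlation). So were mesoderm and mesenchyme genes (10 of 23 were lower and 3 were higher, camera adjusted p = 0.017, but adjusted p = 0.81 with an estimated correlation, and adjusted p = 0.17 with quantile scaling). When adjusted over the list alone, the higher and lower members were the same except for dorsal telencephalon (16 and 2), ribosomal proteins (0 and 16), WNT targets (11 and 0), nodal and left-right targets (1 and 6) and mesoderm and mesenchyme (5 and 11). In all 7193 genes differed, 4128 higher and 3065 lower in the Cortecon run (limma, adjusted p under 0.05), and 7838 without the libraries whose reads stand in both runs. Over all 7 shared days 15235 of 17640 genes changed differently between the runs (limma F-test), 14536 without the shared libraries.

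**Figure D4:**
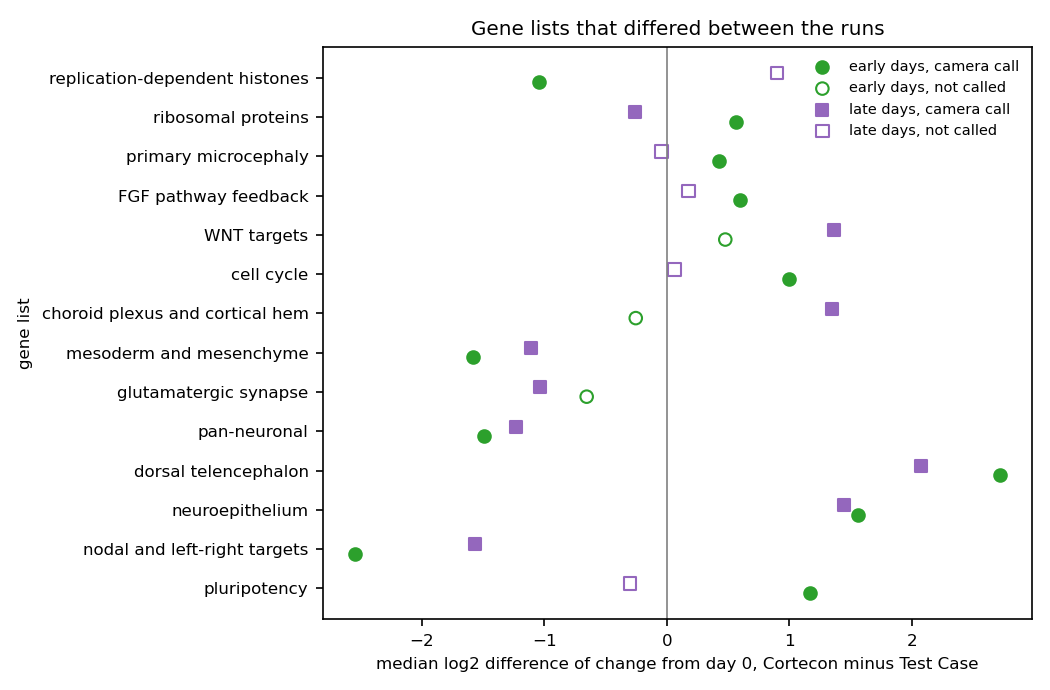
Log2 difference in the change from day 0, Cortecon minus Test Case, for gene lists that differed between the runs, on the early days (7, 12 and 19) and the late days (33, 49, 63 and 77). Filled marks are lists called by camera, and the neuroepithelium and dorsal telencephalon lists lie above 0 and the pan-neuronal list below 0 on both sets of days.

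Each Test Case day was also matched to the Cortecon days by the Spearman correlation of changes from day 0 across 17640 genes, which are not independent replicates. Test Case days 7, 12 and 16 correlated best with Cortecon day 19 (0.864, 0.886 and 0.891), and days 19, 25 and 33 with Cortecon day 77 (0.890, 0.905 and 0.890). Day 49 correlated best with Cortecon day 63 (0.965), which holds the same reads, and days 63 and 77 with Cortecon day 77 (0.874 and 0.864). Thus 8 of the 9 Test Case days were closest to a later Cortecon day, in every fit that left out 1 library, and 7 of 8 without the shared libraries. Test Case day 77 could not have a later match, since the Cortecon run ends on day 77. Some margins were small, as Test Case day 19 correlated at 0.883 with Cortecon day 63. The matching was not repeated with thinned libraries or without the deeper libraries of Cortecon day 77.

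**Figure D5:**
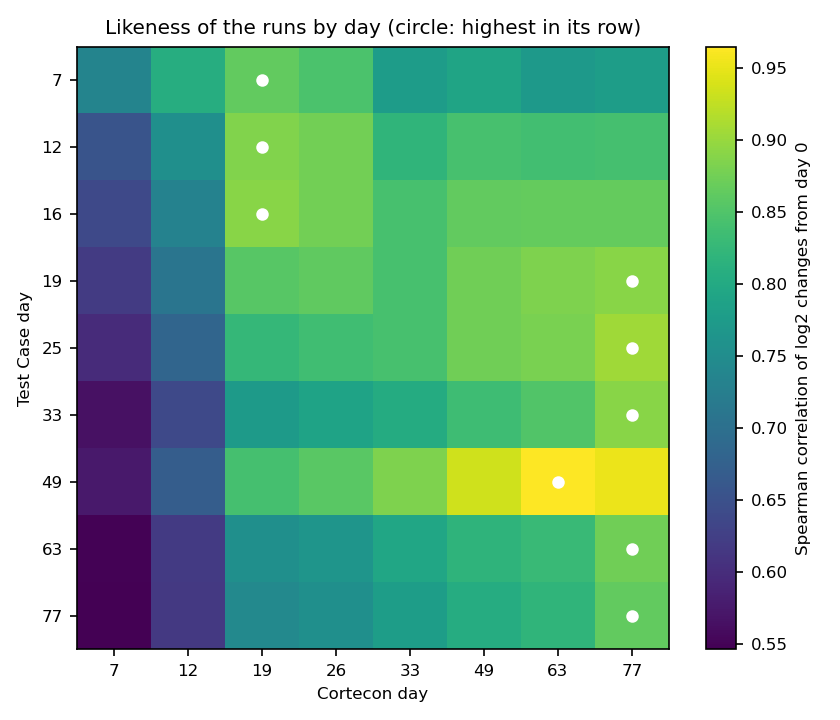
Spearman correlation across genes of the log2 changes from day 0 between each Test Case day (rows) and each Cortecon day (columns), as a colour scale. White circles mark the best Cortecon day of each Test Case day, which lies at day 19 for Test Case days 7 to 16 and at day 63 or 77 after that.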

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

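The tests of the shared reads and of the late neuroepithelial difference, and the splits that keep libraries of one day and number series together, were chosen after the results were seen. In the 3 groups of 4 libraries (Cortecon days 0, 7 and 19) 42 values were checked, marker levels and total reads, and in 0 of them a library stood apart by Dixon's test. Each of these groups holds 2 pairs of closely alike libraries, where a single library can hardly stand apart. The results that drew attention, 77 in all, were differences between the runs, each from a test of the difference itself. They are given as log2 differences, Cortecon minus Test Case, in the change from day 0. For genes near 0 on a compared day they can also hold the difference in scale between the tables. Genes that differed numbered 8074 on the early days, 7193 on the late days and 15235 over the time course.

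On the early days the list medians were 0.99 for cell cycle, 1.56 for neuroepithelium, 0.56 for ribosomal proteins, 2.72 for dorsal telencephalon, 0.43 for primary microcephaly, 0.59 for FGF pathway feedback and 1.17 for pluripotency genes. They were -1.49 for pan-neuronal genes, -1.04 for replication-dependent histones, -2.54 for nodal and left-right targets and -1.58 for mesoderm and mesenchyme. Among single genes the early difference was 7.27 for WNT7B, 6.66 for FEZF1, 6.51 for NR5A1, 6.50 for ANKRD34B and 6.44 for NOS2. It was 6.34 for SIX3, 6.11 for LHX5, 5.92 for FEZF2, 1.59 for UBE2C, 1.54 for BIRC5, 0.91 for RPS19 and 0.75 for RPL35. Lower early values were -6.89 for SOST, -6.48 for MYBPC1, -6.48 for TTR, -5.83 for TMEM26 and -3.01 for ELAVL3. For C6 (-6.34), TYR (-5.84) and MYT1L (-2.88) a day 0 group was listed at 0 in every library, so that the fitted value depends on the added 1, and edgeR did not call them (adjusted p = 0.089, 1 and 1). Of the markers, PAX6 differed by 2.15, EMX2 by 2.87 and POU5F1 by 2.04. The call of POU5F1 was lost with a pseudocount of 5 (0.58, limma adjusted p = 0.16) and with thinned libraries (1.38, limma adjusted p = 0.31). It was also lost without replicate A of Cortecon day 12 (1.81, limma adjusted p = 0.051) or the second Test Case library of day 12 (1.81, limma adjusted p = 0.052). The early difference of MKI67 was 0.83, of BCL11B -1.62, of CUX2 -0.996 and of DCX -2.42. From day 0 to day 7 of the Cortecon run, however, MKI67 changed by -0.88 within series 86 to 104 and by 0.81 within 212 to 298. CUX2 changed by -0.37 and 0.38 there. The early difference was not fitted within a series, for these genes or for the cell cycle list.

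On the late days the medians were 1.44 for neuroepithelium, 2.07 for dorsal telencephalon, 1.35 for choroid plexus and cortical hem and 1.36 for WNT targets. They were -1.23 for pan-neuronal genes, -0.26 for ribosomal proteins, -1.03 for the glutamatergic synapse, -1.57 for nodal and left-right targets and -1.11 for mesoderm and mesenchyme. The late difference was 7.26 for MMRN1, 6.64 for SIX3, 5.63 for LGI1, 5.48 for FEZF2, 4.77 for ZBTB16, 4.74 for RSPO2 and 4.36 for WNT3A. Lower late values were -5.40 for ITGBL1, -5.07 for GFAP, -4.98 for MIR9-1HG, -4.87 for CD34, -4.63 for EBF2, -4.55 for OGN, -2.53 for RBFOX3, -0.61 for RPS18 and -0.51 for RPS6. For MCIDAS (5.95), CIMIP1 (5.86), MYT1L (-2.68) and DMRT3 (5.41) a day 0 group was again listed at 0, and edgeR called CIMIP1, MYT1L and DMRT3 no longer (adjusted p = 1, 1 and 0.91). Of the markers, NANOG differed by -1.60, PAX6 by 1.30, EMX2 by 1.24, TBR1 by 4.09, CUX1 by 0.64, BCL11B by -1.04 and DCX by -1.11. NANOG stood at 0.600 normalised reads or less on each late day of both runs. Its difference therefore comes from the day 0 levels of the separately normalised tables (653 in the Cortecon run and 214 in the Test Case run). With edgeR the late calls of NANOG, EMX2, TBR1, DCX and OGN were lost (adjusted p = 1, 0.16, 0.13, 0.052 and 0.15). The call of NANOG was also lost with a pseudocount of 0.5 and with thinned libraries (limma adjusted p = 0.067 and 0.065). Leaving out the first Test Case library of day 0 ended the calls of EMX2 (0.33, limma adjusted p = 0.41), BCL11B (-0.92, limma adjusted p = 0.074) and DCX (-1.29, limma adjusted p = 0.076). That of DCX was lost on leaving out any of 13 libraries (-1.29 to -0.90, limma adjusted p = 0.053 to 0.20), which in the Cortecon run were C and D of day 0, A and B of day 33, B of day 49 and A of days 63 and 77. In the Test Case run they were both of day 0, the second of days 33, 49 and 63 and the first of day 77. DCX was not called with quantile scaling (-0.79), without the filter (-1.11) or with thinned libraries (-1.02) either.

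The same reads stand under Cortecon day 63 and Test Case day 49, so at least one of these labels is wrong for them. The Test Case day 49 libraries correlated more with Cortecon days 49 and 77 (mean r across genes 0.980) than with Test Case days 33 and 63 (0.917), a difference of 0.0631. An origin in the Test Case run would need a difference below 0, so that the same value argues against that origin. A candidate explanation is that the libraries came from the Cortecon run and were entered in the Test Case table by mistake, but an origin in another culture was not tested.

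Neuroepithelial genes were lower late in the Test Case run, with a median difference of 1.44. Depth is argued against by the median of 1.67 with every library thinned alike. With recomputed TMM factors the median was 1.47, which cannot decide whether a few abundant genes were the cause. The deposited values already matched median-ratio scaling, which limits the weight of such genes as TMM does. Recomputing median-ratio factors moved the median late difference of all genes by -0.0019. A larger share of mesenchymal cells would lower all neural genes alike, but 1 of 24 pan-neuronal genes lay above 0, and 17 were lower in the Cortecon run, which argues against it as the whole cause. The lower start density of the Test Case run, named in the labels, stays open as a biological explanation and was not tested, since density, run and library set cannot be told apart.

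Other splits of the libraries into groups of the same sizes were fitted to see whether chance can be excluded for the counts of called genes, with only the libraries of each comparison in the fit. For Cortecon day 7 against day 0, 1 of 35 splits, the real one, called as many genes. For the later Cortecon comparisons 1 of 100 splits drawn did in each case, as for Test Case days 25, 33 and 49 against days 12, 16 and 19, and for Test Case days 63 and 77 it was 2 of 100. These shares exclude nothing, because the splits that parted libraries of one day and number series called a median of 0 genes in each comparison. Splits that kept such libraries together number 3 for day 7 against day 0 and 10 for each of the others, which is too few for a share under 0.05. Among these, the real split called 13231 genes on Cortecon day 7 (highest other 1), 4260 on days 26, 33 and 49 (3644), 6874 on days 63 and 77 (6170) and 5637 on Test Case days 25, 33 and 49 (2245). For Cortecon days 12 and 19 against day 7 it called 7370 genes, and the split of day 19 from days 7 and 12 called 9197. For Test Case days 63 and 77 it called 2139 genes, and the split that set days 25 and 49 apart from the rest called 6377. That split set days 25 and 49 against days 33, 63 and 77, and day 33 correlated with days 63 and 77 at a mean r across genes of 0.982 and 0.976. Whether the shared libraries of day 49 account for its count was not tested. The other results were not run through splits, because a group held fewer than 3 libraries or no single pair of groups was compared.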

How the results depend on the processing

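Tests without the shared libraries, without day 77, with thinned libraries and with 1 mean per day and number series were chosen after the results were seen. The others were planned. Over the planned settings other than leaving out a library, each count of called genes stayed within 1.5 times of its reported value. Counts were 12566 to 15079 for Cortecon day 7 against day 0 and 9288 to 13228, 9437 to 11236 and 7500 to 11035 for the later Cortecon comparisons. They were 12079 to 13869, 7871 to 8804, 10104 to 11237 and 8815 to 9608 for the Test Case comparisons, and 7539 to 8328 and 6483 to 7540 for the early and late differences between runs. The time courses ranged from 15696 to 20345 (Cortecon), 14787 to 18719 (Test Case) and 13568 to 16735 (between runs). Leaving out 1 library gave 13481 to 14217, 9012 to 10235, 8724 to 10272 and 7839 to 9579 in the Cortecon comparisons and 12011 to 13440, 5840 to 8550, 10273 to 11270 and 8728 to 9427 in the Test Case comparisons. It gave 6283 to 8312 and 5218 to 7380 in the early and late differences, and 8 to 8 in the matching of days. Where a day kept 1 library, it was assumed to vary like the others. With 1 mean per day and number series the Cortecon counts moved to 9286, 3209, 2967 and 1907, in fits with fewer samples.

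Among single genes, results reversed only within a series or without the shared libraries. Within series 86 to 104 CUX2 changed by -0.37 from day 0 to day 7 and PAX6 by 0.17 in the second comparison. Within 212 to 298 MKI67 changed by 0.81 from day 0 to day 7. Without the shared libraries PAX6 and CUX1 stood at -0.0163 and -0.0462 on Test Case days 25 and 33 and MKI67 at -0.135 on days 63 and 77. The cause was not tested for the reversals within a series. Those of the Test Case run came from leaving out day 49, which lay apart from days 25 and 33. PAX6 stood at 4627 normalised reads on day 49, beside 2101 and 2213. CUX1 stood at 4402, beside 3340 and 2654, and MKI67 at 623, beside 1019 and 2023. Of 679 values of named genes, edgeR ended 21 calls and added 5, DESeq2 ended 7 and added 5, quantile scaling ended 6 and added 4 and thinning ended 14. Leaving out the shared libraries ended 13 of 673 and added 6, 1 mean per series ended 46 of 320, and leaving out 1 library changed the call of 42 of the 679 values, in 25 genes. Of 390 list results the estimated correlation ended 104, and fry, which does not compare a list with other genes, called 158 more. Reversed lists were intermediate progenitors with fry on Test Case days 25, 33 and 49 (adjusted p = 2.76e-05, up) and ribosomal proteins with quantile scaling on Test Case day 7 (adjusted p = 0.0266), again without a test of the cause. Recomputed scaling factors moved 11 of 494 marker levels by more than their spread.

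The replicate letters A to D do not pair the libraries, since of 78 pairs of same-letter libraries of different days 5 correlated over 0.1 in their deviations (range -0.235 to 0.226, median 0.00837). Of 24 libraries 8 correlated best with their own letter. With the letter as a replicate block 14170, 10151, 10259 and 9500 genes were called in the Cortecon comparisons and 18028 in the time course. Calls ended for BCL11B and MKI67 in the second (limma adjusted p = 0.053 and 0.085), EMX2 in the third (0.077) and the p53 and DNA damage list in the fourth (camera adjusted p = 0.058). Calls were added for PAX6 and DCX in the third (-0.39 and 0.83, limma adjusted p = 0.0079 and 0.010) and for the oligodendrocyte lineage and the mesoderm and mesenchyme lists in the second (camera adjusted p = 0.039 and 0.039). The fit with the number series as a batch term called PAX6 and DCX in the third comparison too (limma adjusted p = 0.0011 and 0.00051), and among named genes it ended 8 calls and added 3. The Test Case libraries carry no letters, and the numbers that they do carry were given per day, so that no paired fit of them was made. The lowest total was 12536846 reads, in a library listed under Cortecon day 63 and Test Case day 49, and with all libraries thinned to that depth the 14 calls of named genes were not made.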

Other observations

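The lists of motile cilia and lens genes were written, and the tests on them chosen, after related genes had been seen among the largest changes. Adjusted p-values are Benjamini-Hochberg values over these 3 lists in all comparisons, and 2 raw camera p-values are named as such. Of 23 measured genes of motile cilia, which beat on ependymal and airway cells, 17 rose and 3 fell by day 7 of the Cortecon run (median 1.01, camera adjusted p = 0.00043, but adjusted p = 0.14 with an estimated correlation). On days 12 and 19 against day 7, all 23 rose, with a median of 2.31 (log2, raw camera p = 2.04e-17, camera adjusted p = 1.5e-16, and adjusted p = 0.0081 with an estimated correlation). CCNO, needed to multiply centrioles, rose by 6.43 ± 0.33 (log2 ± SE, n = 6 and 4), the assembly factor ZMYND10 by 5.51 ± 0.15, the dynein chain DNAI2 by 5.33 ± 0.31 and FOXJ1, the regulator of the motile cilia program, by 2.60 ± 0.12. Of these, 21 were called higher (camera adjusted p = 2.4e-07) on days 26, 33 and 49 against the average of the low day 12 and day 19. Against day 19 alone 20 of the 23 had a lower mean on day 26, 21 on day 33 and 15 on day 49, which was not tested. FOXJ1 stood at 2117 ± 384 normalised reads (mean ± SD) on Cortecon day 12 (n = 2), 13679 ± 1412 on day 19 (n = 4), 7584 ± 645 on day 26 (n = 2) and 7562 ± 221 on day 33 (n = 2). On days 63 and 77, 17 rose and 1 fell (camera adjusted p = 4.3e-08). In the Test Case run 21 had risen by day 7 (camera adjusted p = 3.0e-09, but adjusted p = 0.14 with an estimated correlation). Of these genes 23 rose on days 12, 16 and 19 (camera adjusted p = 1.5e-16, but adjusted p = 0.055 with an estimated correlation). After that 22 members fell (camera adjusted p = 1.5e-09, but adjusted p = 0.14 with an estimated correlation). Then 23 fell (camera adjusted p = 2.6e-20, and adjusted p = 0.038 with an estimated correlation), and without day 49, 22 fell in each step. FOXJ1 stood at 11725 ± 571 normalised reads (mean ± SD, n = 2) on Test Case day 16, 1008 ± 245 on day 33 and 10156 ± 1041 in the shared libraries of day 49. It stood at 480 ± 195 on day 63 and 372 ± 33.7 on day 77, whereas the Cortecon level was 11159 ± 782 on day 77. On the early days 21 members were lower in the Cortecon run (median -2.24, camera adjusted p = 5.4e-14). On the late days 23 were higher (median 2.03, camera adjusted p = 7.9e-17, and median 2.62 without the shared libraries).

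Crystallins, the main proteins of the eye lens, rose in both runs. Of 14 measured members 11 rose in the Cortecon run by days 26, 33 and 49 (limma, median 4.66) and 13 on days 63 and 77 (median 4.50). Because 8 of these 14 had been seen among the largest rises of these comparisons, a test of the list there would restate that choice. Of the other 6, CRYAB, CRYGB, CRYGC, CRYGD, CRYGN and CRYGS, 4 rose in the first step and 5 in the second. In the Test Case run 13 of 13 rose on days 25, 33 and 49 (median 8.29, camera adjusted p = 5.5e-11, but adjusted p = 0.11 with an estimated correlation, and median 7.23 without day 49). CRYAA was the gene with the most reads in a Cortecon library, up to 1.16% of its reads, and COL1A1, a fibrillar collagen, took up to 4.81% in a Test Case library.

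Of the lens genes other than crystallins, 10 of 15 rose and 1 fell in the step to days 63 and 77, and the lens fibre genes MIP and BFSP2 rose by 5.23 ± 0.36 and 5.23 ± 0.44. Reads shared within the crystallin family stay open for single members, since other lens genes can rise with or without them. With every library thinned to the same depth, 13 of the 13 crystallins called as risen were still called, which argues against depth. A candidate explanation is the presence of cells of the lens lineage, since the lens genes other than crystallins were called up (raw camera p = 0.000108, camera adjusted p = 0.00023), but adjusted p = 0.10 with an estimated correlation. The other lens genes were also called up on Cortecon days 26, 33 and 49 (camera adjusted p = 1.7e-05) and Test Case days 25, 33 and 49 (0.00038). With an estimated correlation these calls were lost (camera adjusted p = 0.055 and 0.38). On Cortecon days 12 and 19 crystallins were called up and the other lens genes were not (camera adjusted p = 0.012 and 0.17). The same held on Test Case days 63 and 77 (camera adjusted p = 0.0016 and 0.44), although without day 49, 6 of the other lens genes rose and 1 fell. Neither of these 2 crystallin calls was kept with an estimated correlation (camera adjusted p = 0.24 and 0.43). On day 0 already, 5 of the lens genes other than crystallins stood at 50 normalised reads or more (BFSP1, EPHA2, HSF4, MAF and TDRD7). PITX3 is also in the midbrain list, and transcription outside the lens was not tested.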
